A study of Mus musculus with 5 samples.

How the data were processed

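Comparisons in 5 settings were made on 5 mouse 2-colour microarrays, each of which compared cells carrying wild-type IL7R (WT) with cells carrying a mutant IL7R, named INS in the labels. Each array held 1 comparison, the cells of each sample had been pooled, and no comparison had a replicate or a dye swap. Per the labels, total RNA was amplified to amino allyl aRNA and coupled to Cy5 for WT and to Cy3 for INS, following the array maker's protocol. The deposited scanner files hold an intensity for each spot at 635 nm (Cy5) and 532 nm (Cy3), on a linear scale, with the local background around the spot in separate columns. Per the file headers, the ratio is 532 nm over 635 nm, and the header fields for normalization and background subtraction are empty. The image software is not given in the sources used here. The dyes in the labels, the ratio in the headers and the sample titles all give INS over WT, which is the direction of every ratio below.

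The authors' deposited value table holds log2 ratios of the same arrays, with scale, centring and direction unstated. Against the scanner values it followed log2 of 532 nm over 635 nm after subtraction of the blank spots, with a Pearson r across probes of 0.701 to 0.951. Its column medians were -3.8e-05 for the CLP culture, -4.8e-05 for the B cells, 0 for the KSL culture, -1.8e-05 for T-ALL and 4.3e-06 for the CMP. Scale, centring and direction were settled by this comparison, and the exact background and filter the authors used stay unknown. The table left 4232 to 8850 of 23473 probes empty, mostly dim ones. It served as an alternative only.

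Spot intensities were corrected with limma 3.58.1 in R 4.3.3, by normexp with an offset of 50 on the foreground medians. The local background was not subtracted, because it held part of the signal of bright spots: around the 24 spots of a positive control in the CLP culture it had a median of 7686 at 532 nm, against a foreground of 18394. This choice was made after the files had been examined, since the plan named normexp and the offset but not which background enters it. Ratios were then normalized within each array by loess (span 0.3), with control spots at weight 0. Only 1 probe was spotted 2 times, and its spots were averaged. A probe counted as detected in a channel when its signal exceeded the mean of the blank spots by 2 SD, with 5% of the 2736 blank spots trimmed at each end. Probes detected in at least 1 channel were compared, and a probe counted as higher or lower in INS from a 2-fold difference on.

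With 1 array per comparison there is no spread between samples, so no p-value was computed for any array. Because the offset compresses ratios, the steps were tested on simulated arrays with known changes. Bright simulated probes were those detected in both channels of an array, at or above the median intensity of its detected probes. Among them, a true 2-fold change reached the 2-fold line for 7.69% to 23.5% of 16 to 26 probes per array. A true 4-fold change did so for 77.8% to 100% of 18 to 26 probes per array. Counts of 2-fold probes therefore leave out many true 2-fold changes. No unchanged bright probe reached the line, but the simulation held only spot and background noise and a smooth dye trend. It had no spread between samples and no dye bias of single probes, so it gives no rate of false 2-fold probes. Relations between arrays were Pearson correlations across probes, which are not independent replicates. Their 95% intervals came from 1000 bootstrap draws of the 24 printing blocks and cover position on the array only. The numbers expected for shared probes assume independent lists. Probes moving the same way in all 5 settings were sought with limma (intercept only, two-sided, Benjamini-Hochberg at 0.05), in which the spread between settings is the error.

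The probe IDs carry no gene name in the files used here, and 0 of 23473 IDs were found in the reference table of gene names. The 33 gene lists and cell type markers chosen in advance, the level of Il7r, and the rules for several probes of a gene could therefore not be evaluated. The rule for named genes took, per array, the 12 highest and 12 lowest log2 ratios among probes with a symbol that were detected in both channels, not saturated, and at or above the median intensity of detected probes. It was applied to probe IDs without the symbol, and 2 IDs each way are printed per comparison. In place of gene lists, the 200 probes most selective for 1 array were taken by intensity alone. These are the probes brightest on that array relative to the highest of the 3 arrays other than the one tested. Their median log2 ratio on the tested array was set against 10000 random sets matched on intensity in 20 bins. These sets were added after the files had been examined.

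Alternatives fixed before the data were examined were median centring without loess, plain subtraction of the local background, an offset of 10, loess within printing blocks, no filter on dim probes, detection in both channels, the authors' value table, and leaving out each array in turn. Subtraction of the blank mean, normexp with the local background and a restriction to bright probes were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.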

Results

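The study set cells with wild-type IL7R (WT), the receptor chain for interleukin-7, against cells with the mutant IL7R named INS, in culture and after transplantation. Retrovirally transduced Balb/c mouse cells were compared in 5 settings, with 1 array for each. The CLP culture held transduced CLP cells, the lymphoid progenitors, grown for 5 to 7 days on OP9 stroma with SCF, IL-7 and Flt3 ligand and sorted for GFP. The CLP-derived B cells were IgM+B220+ cells from recipients irradiated with 4 Gy, around day 60, and the labels call the INS cells leukemic. The KSL culture held transduced KSL cells, a stem and early progenitor fraction, grown for 4 to 5 days with added cytokines. Its description opens with the words in vivo, while its title and the rest of the description give a culture, and it was taken as one. ICN T-ALL cells were T-cell leukemias from KSL cells that also received intracellular Notch1, taken at day 30 to 40. The KSL-derived CMP cells were a myeloid progenitor fraction sorted around day 40.

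Of 23473 probes, 76.0% to 83.2% were detected per channel on 4 arrays. The CMP array was dimmer, with 58.2% detected in INS and 71.4% in WT. Spots that hold no probe passed the same limit in 14.2% to 20.4% of cases in INS and 35.5% to 52.8% in WT, highest in WT on the CMP array, so a detected probe is not necessarily an expressed one. The 24 spots of each of 2 positive controls had an SD of the log2 ratio of 0.07 to 0.13 within an array, which covers spotting and scanning only. Their mean log2 ratios were not near 0 on every array and lay apart on the same one, at 0.93 and -0.70 in the CLP culture and at -0.76 and -0.97 in the B cells. One control had a median signal of 263 in INS and 364 in WT on the CMP array, against 13633 to 24309 in INS on the other arrays. What the controls bind is not given in the sources used here. Sample-to-sample spread was not measured, the number of arrays limits the precision, and no difference below has a replicate check. Dye and genotype ran together on all 5 arrays. Folds include the compression by the offset. Across the other settings tried, 15 of the 20 named ratios (19 probes, M200001877 being named on 2 arrays) moved by over 1.5 times in fold, and none changed direction. An offset of 10 by itself moved 4 of the 20. Probes are given by ID because the files used here do not pair them with genes.

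**Figure D1:**
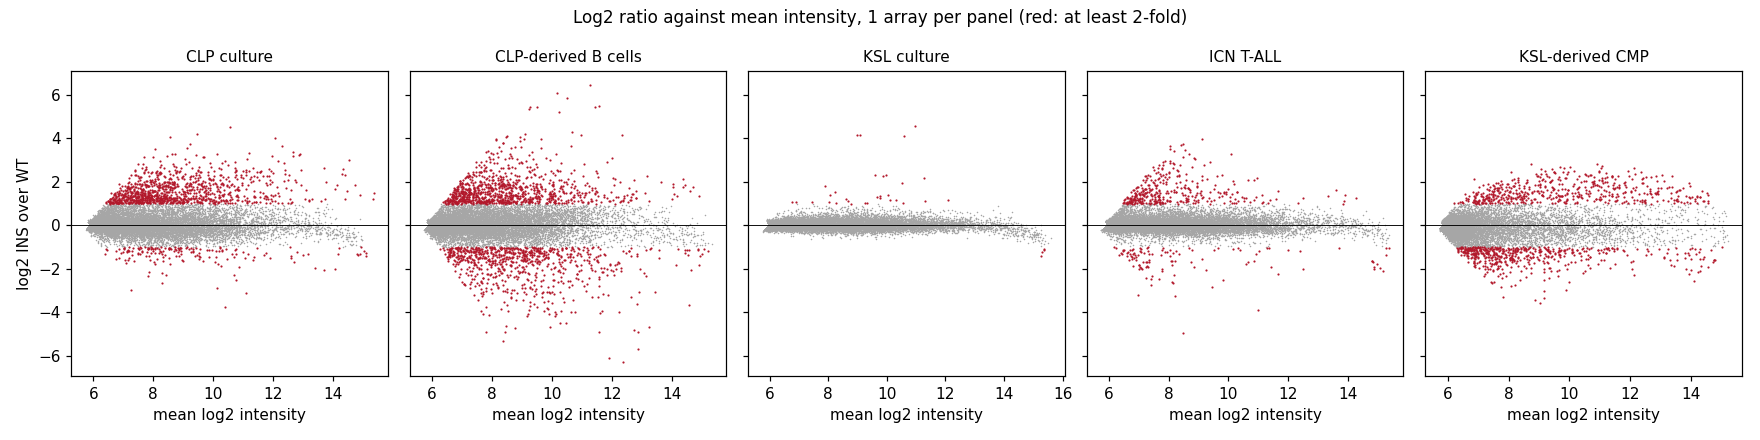
Log2 ratio of INS over WT (vertical axis) against mean log2 intensity (horizontal axis) for each detected probe, 1 array per panel, with probes at least 2-fold apart in red. The KSL culture has 31 such probes above 0 and 4 below, and its brightest probes bend below 0 after loess.

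In the CLP culture, 1015 of 20145 probes were at least 2-fold higher in INS and 172 lower. M200001877 had the highest named ratio, 23.0-fold higher in INS, with a signal of 7837 in INS and 254 in WT. M200000886 was 18.4-fold higher. M200000431 was 13.5-fold lower in INS (signal 383 against 4511) and M300005701 was 8.56-fold lower. The 12 highest probes were 9.83-fold to 23.0-fold higher, and the 12 lowest 4-fold to 13.5-fold lower. The authors' value table gave 2166 higher and 695 lower probes, and subtraction of the local background gave 2941 and 2256 (56.6% higher, against 85.5% in the main setting).

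CLP-derived B cells had the widest differences among the named probes. In INS, 969 of 19852 probes were at least 2-fold higher and 788 lower. M400011281 was 88.9-fold higher in INS (signal 33441 against 146) and M200001605 was 67.7-fold higher. M400011025 was 77.8-fold lower (839 against 33934) and M200002417 was 67.5-fold lower. Among the 12 probes lowest in INS B cells, 11 were at least 2-fold higher in the INS CLP culture. Of the 12 highest, 7 were at least 2-fold lower there and 2 at least 2-fold higher. M200001605 ran from 47.0-fold to 192-fold across the other settings. Median centring without loess changed the split to 2533 higher and 420 lower, and the authors' value table gave 2252 and 1611.

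The KSL culture had the fewest probes apart, with 31 of 19244 at least 2-fold higher in INS and 4 lower. M300003688 was 23.7-fold higher (signal 13290 against 260) and M400011276 was 17.8-fold higher. They belonged to 4 probes that were 17.5-fold to 23.7-fold higher, while the fifth highest was 5.07-fold higher. M200001877, highest in the INS CLP culture, was 2.68-fold lower here, and M400007104 was 2.35-fold lower. Both lay near the top of the scale, with signals of 29746 and 33023 in INS and 50993 and 49939 in WT, where loess left ratios below 0. The authors' value table gave 221 higher and 44 lower probes, and subtraction of the local background gave 1193 and 1202, with no lean to higher. Median centring moved the median of all detected probes to 0.12 on the log2 scale.

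In ICN T-ALL, 351 of 19363 probes were at least 2-fold higher in INS and 116 lower. M300014777 was 15.9-fold higher (signal 2947 against 67) and M200005978 was 13.3-fold higher (7.34-fold to 42.0-fold across the other settings). M300006927 was 30.9-fold lower (86 against 1470; 10.4-fold to 126-fold across the other settings) and M400007350 was lower with a log2 ratio of -3.90. Of the 12 probes lowest in INS T-ALL, 7 were also at least 2-fold lower in INS B cells and 1 higher. Of the 12 highest, 6 were at least 2-fold higher there and 1 lower. Median centring changed the split to 647 higher and 86 lower, the authors' value table gave 1122 and 292, and subtraction of the local background gave 2100 and 1660.

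KSL-derived CMP cells had about as many probes higher as lower: 524 of 17281 were at least 2-fold higher in INS and 540 lower. M400006908 was 7.18-fold higher (signal 5040 against 683; 6.78-fold to 19.0-fold across the other settings) and M200005353 was 7.02-fold higher. M200012730 was 11.7-fold lower (122 against 1869) and M200004063 was 10.8-fold lower. None of the 12 highest probes was 2-fold apart in either culture or in T-ALL. Median centring changed the split to 461 higher and 788 lower, and the authors' value table gave 1613 and 2212. Normexp with the local background, added after seeing the data, turned the lean to 559 higher and 370 lower. On simulated data a 3-fold change reached the 2-fold line for 33.3% of only 15 bright probes on this array. On the others it did so for 80.8% to 89.3% of 20 to 28 probes per array.

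Because the arrays differed in brightness, counts were also taken over 6094 bright probes. These were detected in both channels of all 5 arrays, with a log2 intensity, averaged over the arrays, at or above the median of such probes. A probe of this set can still be dim on 1 array. In this set 16.3% of probes were at least 2-fold apart in the B cells and 15.4% in the CMP. The share was 9.75% in the CLP culture, 3.30% in T-ALL and 0.197% in the KSL culture. The SD of the log2 ratio over these probes ran from 0.22 in the KSL culture to 0.87 in the B cells. This set was chosen after seeing the data. Its shares are of single arrays. Only those of the CMP and the KSL culture were compared, further below, with an interval that covers position on the array and not the spread between samples.

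**Figure D2:**
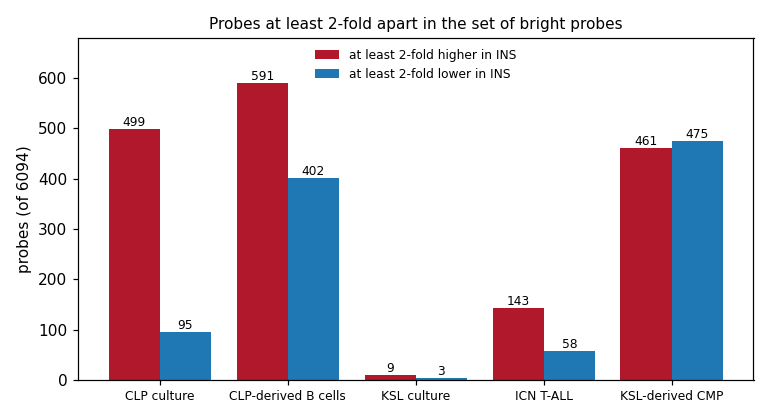
Number of probes (vertical axis) at least 2-fold higher (red) or lower (blue) in INS on each array, out of 6094 bright probes. The KSL culture has 9 and 3, and the B cells have 591 and 402.

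Log2 ratios in the CLP culture and in the B cells ran in opposite directions across 19043 probes (Pearson r = -0.276, 95% bootstrap interval over printing blocks -0.304 to -0.25; Spearman rho = -0.206). Of these, 217 probes were at least 2-fold higher in the INS culture and lower in INS B cells, against 39.4 expected for independent lists. The reverse held for 74 probes against 8.65 expected, and 61 went the same way on both against 55.8 expected. With the local background subtracted, an alternative fixed beforehand, r was -0.107. With normexp and the local background, a setting added after seeing the data, r was -0.114.

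The 2 cultures shared 20 of the probes higher in INS, against 1.61 expected, and r was 0.224 (0.117 with the local background subtracted and 0.115 with the blank mean subtracted). The number shared was 32 with an offset of 10, 62 with median centring, 92 in the authors' value table, 163 with the blank mean subtracted and 205 with the local background subtracted. It was 31 with normexp and the local background, and 4 among bright probes (0.737 expected). For the other settings no expected number was computed. A larger number shared is not by itself a stronger overlap, because the lists differ in length between settings. With the local background subtracted, 2941 probes were higher in the CLP culture and 1193 in the KSL culture, against 1015 and 31 in the main setting. On the other arrays, which played no part in choosing these 20 probes, their median log2 ratio was 0.37 over the 15 measured in T-ALL and -0.06 over the 12 measured in the CMP. In the B cells it was -0.06 over 18, which ranged from -3.45 to 2.21. The CLP culture and T-ALL shared 107 higher probes against 16.9 expected, with r = 0.232. B cells and T-ALL had 121 probes at least 2-fold in the same direction (21.1 expected) and 81 in opposite directions (19.4 expected), with r = 0.031. For this pair r was 0.233 with median centring and 0.107 with normexp and the local background. In all, 10 pairs of arrays were compared. Probes are not independent replicates, and a dye bias of single probes would also give positive correlations.

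**Figure D3:**
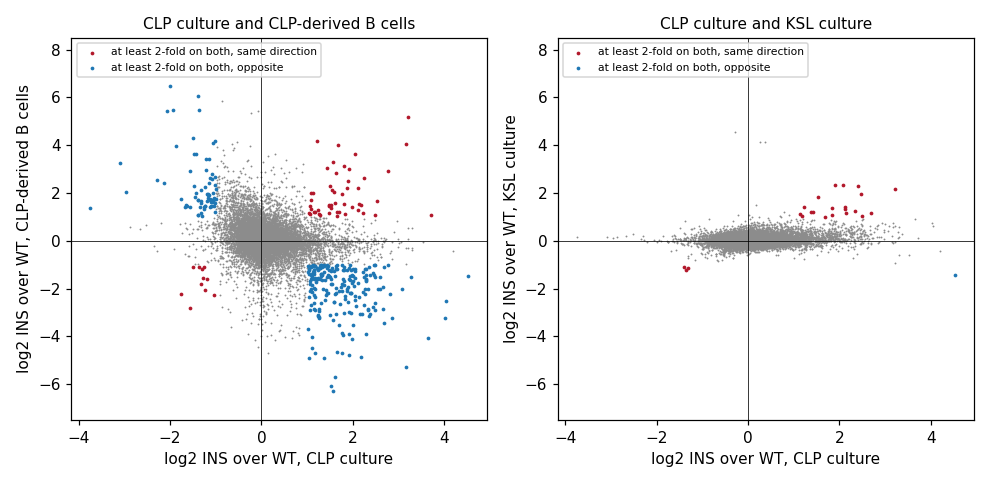
Log2 ratio of INS over WT in the CLP culture (horizontal axes) against the B cells and the KSL culture (vertical axes), 1 point per probe. Probes at least 2-fold apart on both arrays are red where the direction is the same and blue where it is opposite, and 217 blue points lie at lower right in the B-cell panel.

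No probe was called across the 5 settings by limma (0 of 15977, smallest adjusted p = 0.304), and 671 had an unadjusted p under 0.05 against 799 expected. M400007104 had the smallest p, with a mean log2 ratio of -1.10 ± 0.09 (SE) and values below 0 on 5 of 5 arrays (limma adjusted p = 0.304). M200007160 followed with a mean of 1.00 ± 0.09 (SE), above 0 on 5 of 5 arrays (limma adjusted p = 0.304). At least 2-fold differences in the same direction on 3 or more arrays were found for 25 probes higher in INS and 6 lower. Among 15977 probes detected on all arrays these were 24 and 6, against 3.32 and 0.399 expected for independent lists. None reached all 5. The probes lower on 3 or more arrays included M400007104, M400002052, M400010868, M400009918 and M400002879. In the KSL culture these named probes had signals of 33023 to 43773 in INS and 41494 to 50913 in WT. That is near the top of the scale, where loess left ratios below 0 on that array. Whether such a bend accounts for their low ratios was not tested, so the 6 lower probes need not be shared effects of INS. Of 3598 probes at least 2-fold apart on any array, 2821 were so on 1 array only and 436 were higher on 1 and lower on another.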

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

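For the results here and among the other observations, 13 tests of explanations were run. Of these, 6 were chosen only after the result was seen: the tests of the local background, of the selective probes as carriers, of a dye bias in the KSL-selective set and in the relation of CLP culture to T-ALL, of KSL-type cells or RNA, and of donor animals.

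A difference between settings stood out: 291 probes were at least 2-fold apart in opposite directions in the CLP culture and the CLP-derived B cells, against 48.1 expected for independent lists. The difference was not tested, since each setting has 1 array.

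Among bright probes r was -0.315 (95% interval -0.345 to -0.283), so the relation was not confined to probes dim on average. Noise of dim probes that is independent between arrays would pull r toward 0, so the outcome of this test was settled beforehand. Position on the array was argued against, because r was -0.281 (-0.309 to -0.254) with loess within printing blocks. B-cell-selective probes lower in the INS CLP culture were predicted before the result was seen, although the sets were added after the files had been examined. Their median log2 ratio of -0.10 lay at percentile 0 of matched random sets (26 of 191 were at least 2-fold lower and 18 higher). But 17 of 20 such comparisons left the random range, so this decides nothing. Without the B-cell-selective and KSL-selective probes r was still -0.282 (-0.306 to -0.256), which argues against these sets as the whole cause. The local background stays open: with it in the correction r was -0.114 (-0.177 to -0.054), an interval that spans the line of -0.1 set for this test. Plain subtraction of the local background, an alternative fixed beforehand, gave -0.107. A difference between the cultured progenitors and the leukemic B cells may underlie the rest, and it cannot be told apart from the local background or from differences between single samples.

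On the CMP array the share of bright probes at least 2-fold apart was 78 times that on the KSL culture array. The 95% interval was 51.2 to 154, so the higher CMP count was not confined to probes dim on average. A probe bright on average can still be dim on the CMP array. M200000327 had a mean log2 intensity of 6.74 there and 11.9 in the KSL culture, and its CMP log2 ratio was -1.05. Noise of probes dim on the CMP array itself therefore stays open as a reason. Among bright probes the covariance of the CLP culture and T-ALL ratios exceeded the whole variance of the KSL culture ratios by 0.0243 (0.0109 to 0.0373). That argues only against a dye bias of equal size on every array as the whole cause. A dye bias that differs in size between arrays stays open. The 2 positive controls had mean log2 ratios of 0.93 and -0.70 in the CLP culture, 0.46 and -0.77 in the KSL culture, and 0.24 and -0.17 in T-ALL.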

How the results depend on the processing

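Subtraction of the blank mean, normexp with the local background and the restriction to bright probes were chosen only after seeing the data. The 20 named ratios (19 probes) kept their direction and stayed at least 2-fold apart under every alternative that measured them, but for 15 of them the fold moved by over 1.5 times in at least 1. The fold of M300006927 ran from 10.4 to 126. Calls across the 5 arrays stayed at 0 under every alternative, bright probes alone and leaving out each array in turn (0 to 0) included. Counts of 2-fold probes depended on the processing, in the order CLP culture, B cells, KSL culture, T-ALL, CMP. With the local background subtracted, 2941, 2887, 1193, 2100 and 2319 probes were higher and 2256, 2837, 1202, 1660 and 3014 lower. With the blank mean subtracted, 2604, 2578, 709, 1605 and 2304 were higher and 1391, 2319, 663, 1064 and 3246 lower. The authors' value table gave 2166, 2252, 221, 1122 and 1613 higher and 695, 1611, 44, 292 and 2212 lower. An offset of 10 gave 1544 higher and 337 lower in the CLP culture, 1460 higher in the B cells, 58 higher in the KSL culture, 630 higher and 189 lower in T-ALL, and 923 higher and 1302 lower in the CMP. Median centring gave 2533 higher and 420 lower in the B cells, 128 higher in the KSL culture and 647 higher in T-ALL. Normexp with the local background gave 69 higher in the KSL culture and 72 lower in T-ALL. The KSL culture had the fewest 2-fold probes under each of these settings. A smaller offset compresses ratios less by construction; the cause of the other shifts was not tested.

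The weak negative correlation of KSL culture and CMP ratios (r = -0.118) turned to 0.012 with the local background subtracted and to 0.02 with normexp and the local background, and was -0.23 with median centring. Median centring also gave 0.489 for KSL culture and T-ALL (from 0.21; 0.103 with the local background and 0.102 with the blank mean subtracted) and 0.335 for B cells and KSL culture (from 0.005). The correlation of CLP culture and B cells fell in size to -0.107 with the local background subtracted and to -0.114 with normexp and the local background. Probes in opposite directions on these 2 arrays (291) numbered 177 among bright probes, 197 with normexp and the local background, 515 with an offset of 10, 827 in the authors' value table, 1062 with the blank mean subtracted and 1095 with the local background subtracted. For independent lists 48.1 were expected in the main setting and 42.1 among bright probes, and the number was not computed for the rest. In the settings with larger numbers the lists of 2-fold probes also grew, so these numbers do not show a stronger relation. Loess within printing blocks and detection in both channels moved no count by over 1.5 times. Leaving out the filter on dim probes changed no count, because no undetected probe was 2-fold apart, so it tests nothing. Averaging several probes of a gene, and all alternatives for gene lists, were not run because the probes have no gene names here. No paired analysis was possible because each comparison has 1 array. Signal over background limits the CMP array most, where 58.2% of probes were detected in INS.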

Other observations

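The selective probe sets below were taken after seeing the files, and of the tests here those of dye bias, of KSL-type cells or RNA and of donor animals were chosen only after the result was seen. The 200 probes most selective for the KSL culture by intensity were higher in INS in the CLP culture. Of 197 measured, 157 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.91 (central 95% of matched random sets -0.03 to 0.08). The probes most selective for the CLP culture had a median of 0.49 in the B cells, where 71 of 189 were at least 2-fold higher in INS and 21 lower. In the KSL culture the CLP-culture-selective set had a median of 0.19. In all, 17 of 20 set comparisons lay outside the central 95% of random sets, where 1 would by chance; random sets ignore that genes move together, so this describes the arrays and is no test.

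For the KSL-culture-selective probes, a dye bias shared by all arrays was argued against as the whole cause, because on the KSL culture array, where they are bright by selection, their median was 0.15 (log2, 95% interval 0.09 to 0.24), and 0.54 with median centring against 1.99 in the CLP culture, so a part stays open. On the other 3 arrays they are dim by selection, and their medians there decide nothing. Uneven hybridisation was argued against because the median was above 1 in 23 of 24 printing blocks. The INS CLP sample may have held more cells or RNA of the kind in the KSL culture, but the test of it, in which 97.46% of the probes lay above 0, restates the median and decides nothing. A change within the CLP-derived cells themselves would give the same values, and these cannot be told apart; the sort for GFP would not remove transduced cells of another type.

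The 4 probes that were 17.5-fold to 23.7-fold higher in INS in the KSL culture included M300003688 and M400011276. By position, M300003688, M400011276 and M400010807 lie in printing block 23 and M400000660 in block 22, of 24 blocks. With loess within printing blocks M300003688 had a log2 ratio of 4.59 and M400011276 one of 4.16. A local defect around the spots was argued against, because 60 probes within 2 rows and 2 columns had a median log2 ratio of -0.002. On the T-ALL array 4 of 4 were lower in INS (log2 -1.63 to -0.73), and in the B cells they lay between 0.58 and 0.79. They did not move together in the CLP culture (-0.28 to 0.38) or the CMP (-0.40 to 0.16). In the CLP culture their WT signals began at 17 against a blank mean of 15.9, and in the CMP at 16 against 13.8. Some therefore lay near the floor on these arrays, where the lack of joint movement decides little. On the T-ALL array their signals lay between 63 and 358 in WT (blank mean 16.2) and between 86 and 221 in INS (63.3). It may be that donor animals of the 2 cell pools differed in these genes, and without gene names this cannot be told apart from an effect of INS in this culture.

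Across the 5 arrays, 16 of 16 sign arrangements gave as many limma calls as the real one, since the real count was 0 and the highest other 0. With 16 arrangements no share under 0.05 can be reached. At an unadjusted p under 0.05 the real arrangement had 671 probes and the highest other 1047.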
